A study of Homo sapiens with 32 samples.

How the data were processed

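RNA-Seq (8 libraries), Subunit-Seq (8 libraries) and m6A-eCLIP (16 libraries) made up the 32 samples in 16 groups of 2. Per the labels' protocols, HEK293T cells in serum-supplemented DMEM were given 600 nM thapsigargin for 16 h, or DMSO. RNA-Seq libraries were made from poly(A) RNA with the NEBNext Ultra II RNA kit. Subunit-Seq used an anti-HA immunoprecipitation of eIF3d carrying a TEV protease site, release of its cap-binding domain by TEV, enzymatic removal of contaminating RNA and the NEBNext Ultra II Directional kit. The m6A-eCLIP libraries were made with a kit from Eclipse Bio. The submitters' processing notes name cutadapt, STAR, DESeq2 and BWA, without versions or roles, and the build GRCh38; they name no gene counter, annotation or site caller.

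The deposited RNA-Seq and Subunit-Seq values are RPKM made by the authors, that is, reads per kilobase of gene scaled to the reads of each library, over 58721 genes with versioned Ensembl identifiers. Symbols were found for 58252 of these (99.2%). The low values of each gene and library are whole multiples of a step, which gave the reads behind each value and an effective length per gene. Of 26179 genes above 0 in at least 3 libraries, a length was found for 26178, and for 26111 of these every value was a whole number of reads within 0.02. The other 67 had at least 1 value that was not, all in Subunit-Seq, where at least 99.8% of values in each library were whole. Depth ranged from 4508483 to 10163214 reads in RNA-Seq and from 5102852 to 16860637 in Subunit-Seq. A count of 0 allows up to 3 reads of that total, and intervals for shares of reads are 95% Wilson intervals. The deposited m6A files are lists of site positions with strand and without score, coverage or replicate. Duplicate entries were removed, 1, 3, 3 and 11 in WT DMSO, WT Tg, DD DMSO and DD Tg. Sites were then assigned by position to RefSeq gene spans of GRCh38, which give no exons here. The strand of a site was not compared with that of the gene, so a gene's count can hold sites on the opposite strand. Of 2794 genes with sites, 2634 (94.3%) were matched to the expression tables.

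Values were analysed as log2(RPKM + 1). RNA-Seq genes needed a mean of at least 1 RPKM over the 8 libraries and Subunit-Seq genes a mean of at least 1 RPKM over the 4 inputs. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with all 4 groups of an assay in 1 fit. Tests are two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The RNA-Seq fit had 4 residual degrees of freedom and a prior of 5.73. The Subunit-Seq fit had the replicate number as a block, because its tables were deposited per replicate. It had 3 residual degrees of freedom and a prior estimated as infinite, so that its p-values and standard errors use the pooled spread alone. The 5 RNA-Seq contrasts were Tg against DMSO in WT and in DD cells, DD against WT in DMSO and in Tg, and their interaction; the 4 Subunit-Seq contrasts were IP against input in each treatment, the difference between these, and input Tg against input DMSO. Error terms are SD between the 2 libraries of a group for RPKM and the standard error (SE) of the fit for log2 differences.

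Of 25 gene lists, those with at least 5 tested members (21 in RNA-Seq, 20 in Subunit-Seq) were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists within each contrast. Camera compares a list with the other genes; fry tests whether the members move one way on balance. Neither the estimated correlation nor fry called any list in any contrast. Medians of a list are given relative to the median of all genes tested, and the same difference was computed from the libraries of each replicate number alone. The lists, the models, the thresholds, the other settings to try and the rule for named genes were chosen before the data were examined. The contrast of IP Tg with IP DMSO, the medians within a replicate number, the definition of a list's value as its distance from the all-gene median, and these alternatives were chosen after: voom weights on recovered reads, with library totals or with median-ratio sizes; a robust prior; each gene's own spread; and the RNA-Seq replicate block together with leaving out the second DD Tg library.

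Named genes followed this rule: EIF3D first; per contrast the 6 largest and 6 smallest log2 differences among called genes whose groups did not overlap and whose mean was at least 5 RPKM; per list up to 4 called members with the largest change, or otherwise the 2 most expressed; always ATF4, DDIT3, EIF2AK4, ALKBH5, METTL3, METTL14, JUN and HSPA5; for the sites, the 5 genes with most sites per list and the ISR, eIF3 and m6A genes with a site. The text prints a part of these. Reads from the EIF3D transgene and the native gene cannot be separated in these tables.

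Site lists were compared by position and strand, within 10 and 50 nucleotides, and by gene. Medians of genes with gained or lost sites were ranked among 10000 random lists matched on deciles of expression. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reads, sites, ranks and plots. The pipeline was tested on simulated data of the same depth in which 200 genes were changed. With a simulated dispersion of 0.02 the RNA-Seq fit recovered 61.2%, 98.5% and 100% of genes changed 2-fold, 4-fold and 8-fold, and with 0.3 it recovered 0%, 10.4% and 31.8%. It also called 14 and 11 unchanged genes at these dispersions. In Subunit-Seq at 0.3 the fit recovered 0%, 2.99% and 30.3% for IP against input in DMSO with 0 unchanged genes called, and 0%, 4.48% and 30.3% for the inputs with 8; at 0.02 it recovered 67.2% and 64.2% of genes changed 2-fold and all those changed more, with 17 and 18 unchanged genes called. Except for IP against input at 0.3, the simulated calls thus held a larger share of unchanged genes than the threshold of 0.05 allows. The median dispersion of the real libraries was 0.267 in RNA-Seq and 0.179 in Subunit-Seq. In the simulation a list of 24 genes changed 2-fold was called by camera (adjusted p = 0.000620, and 0.274 with an estimated correlation). Of 20 other lists 0 were called with the preset correlation. With an estimated correlation camera thus missed a changed list. The lack of such a call therefore does not show that a list stayed the same. Genes were drawn independently, without a difference between replicate numbers. The simulation thus cannot show how often the preset correlation calls unchanged lists in the real libraries. Other settings tried were another pseudocount, 2 other filters, rescaling by median ratios, the replicate block, fitting only the groups compared, leaving out each library in turn, other list tests, and other rules for shared sites and random lists. A stricter score threshold for sites could not be run because the lists hold no score. No reference genome was at hand, so reads were not mapped again.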

Results

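The series measured human HEK293T embryonic kidney cells that carried wild-type eIF3d (WT) or its phosphomimetic DD form, in which serine residues are replaced by aspartate. eIF3d is the subunit of translation initiation factor eIF3 that can bind the mRNA cap. Cells received 600 nM thapsigargin (Tg) for 16 h or the solvent DMSO. Thapsigargin blocks the calcium pump of the endoplasmic reticulum (ER) and so starts the unfolded protein response and the integrated stress response (ISR). RNA-Seq had 4 groups of 2 libraries, WT and DD in DMSO and in Tg. Subunit-Seq, which recovers RNA bound by the cap-binding part of eIF3d and sets it against input RNA, had 4 groups of 2 libraries, input and immunoprecipitate (IP) in DMSO and in Tg. The m6A-eCLIP experiment, which maps N6-methyladenosine in RNA, had 16 libraries, from which 1 list of called sites per genotype and treatment was deposited, so site counts had no replicates and unknown depth.

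The reads behind the RNA-Seq values numbered 7242457 and 4508483 in WT DMSO replicates 1 and 2, 8179644 and 7804214 in WT Tg, 7675001 and 9741732 in DD DMSO, and 10163214 and 6590445 in DD Tg. In Subunit-Seq they numbered 8130736 and 14606555 in input DMSO, 10808590 and 14828186 in IP DMSO, 5102852 and 12027931 in input Tg, and 16860637 and 15816031 in IP Tg. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 took from 25.4% of the RNA-Seq reads (DD DMSO replicate 2; 95% Wilson interval 25.38 to 25.44) to 57.3% (DD Tg replicate 2; 57.24 to 57.32). They took 4.64% (4.63 to 4.66) of reads in input DMSO replicate 1, 20.4% (20.41 to 20.45) in input DMSO replicate 2, 19.9% (19.91 to 19.98) in input Tg replicate 1 and 9.41% (9.40 to 9.43) in input Tg replicate 2. In the IP libraries their share was at most 0.705% (0.701 to 0.709). Intervals cover counting error only. Nothing in the labels says that replicates came from separate cultures. P-values of single genes from limma therefore measure only the spread between samples, which was pooled over genes in Subunit-Seq. Camera's p-values at the preset correlation set a list against other genes, taken as nearly independent. They do not measure the spread between samples.

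In RNA-Seq, the first principal component held 55.6% of the variance and parted replicate 1 (scores of −29.8 or lower) from replicate 2 (52.7 or higher, except DD Tg replicate 2 at 0.65). The second held 22.3% and set DD Tg replicate 2 (75.5) apart from the other libraries (−25.7 to −0.14). Across genes, the difference of replicate 2 from replicate 1 correlated between WT DMSO, WT Tg and DD DMSO (r from 0.743 to 0.864). With DD Tg it correlated less (0.134 to 0.299). In Subunit-Seq the first component held 67.9%, with input DMSO replicate 2 at −132 and the IP libraries between 54.3 and 76.2. Input DMSO replicate 2 had 6395 genes at 1 RPKM or more, against 11452 in input DMSO replicate 1. The difference between replicates correlated with r = 0.002 between input DMSO and IP DMSO. Between the other pairs of Subunit-Seq groups r was 0.210 to 0.510. Effects are therefore also given within each replicate number.

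The first question was whether Tg changed RNA levels in WT cells. The 23 tested ER chaperones and folding factors, which include HSPA5 and HSP90B1, rose relative to other genes, with a median log2 difference of 0.54 against 0.12 for all genes and all 23 members above that all-gene median. HSPA5 (ENSG00000044574.7), the main ER chaperone, averaged 53.0 ± 27.7 RPKM in DMSO and 83.5 ± 19.8 in Tg (SD, n = 2 here and below). The 32 genes of the secretory pathway and ER-associated degradation rose by a median of 0.27 relative to all genes, with 30 members above the all-gene median. The 13 mitochondrially encoded mRNAs, which code for respiratory chain subunits, rose by 0.55, with all 13 above it. The 18 ISR kinases, eIF2 subunits and eIF2 phosphatases rose by 0.20. The 75 cytosolic ribosomal protein mRNAs changed by −0.35, with 3 members above the all-gene median. The 33 targets of the ISR transcription factors ATF4 and CHOP had a median only 0.02 above all genes, with 18 members above it, and did not pass (adjusted p = 0.356). Their median and mean (0.05) were positive while the test's direction was negative. ATF4 (ENSG00000128272.14) averaged 263 ± 7.24 RPKM in DMSO and 269 ± 63.9 in Tg, DDIT3 (ENSG00000175197.12), which codes for CHOP, 20.48 ± 5.36 and 25.8 ± 7.63, and EIF3D (ENSG00000100353.17) 69.0 ± 0.897 and 67.7 ± 33.2.

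No single gene passed in WT cells: limma called 0 of 9637 genes, limma with voom weights on recovered reads also called 0, and 24 genes had an unadjusted p under 0.05 where chance alone gives 482. Here and in the RNA-Seq contrasts below, the main fit counted the difference between replicate numbers as spread. Its few small p-values therefore do not show that RNA levels stayed the same. With the replicate number as a block 0 genes passed (67 at an unadjusted p under 0.05), and with the block and without DD Tg replicate 2 also 0 (459). Camera with its preset correlation gave an adjusted p of 2.68e-06 for ER chaperones (adjusted p = 0.327 with an estimated correlation), 5.72e-05 for the secretory list (0.708 with an estimated correlation) and 0.000116 for mitochondrial mRNAs (0.327 with an estimated correlation). It gave 0.0455 for the ISR kinase list and 1.69e-08 for ribosomal proteins, both with adjusted p = 0.708 with an estimated correlation. Adjusted over the list alone, 0 members of any list passed in this or any other RNA-Seq contrast. The other 16 lists did not pass, with adjusted p from 0.156 to 0.957. Within replicate 1 and replicate 2, medians relative to all genes were 0.07 and 0.79 for ER chaperones, 0.31 and 0.41 for the secretory list, 0.17 and 0.32 for ISR kinases, 0.70 and 0.45 for mitochondrial mRNAs, −0.35 and −0.38 for ribosomal proteins and −0.07 in both for ISR targets. As the RNA-Seq fit had no block, leaving out 1 library set unequal replicate numbers against each other, so calls lost or gained that way, here and in the RNA-Seq contrasts below, also carry the difference between replicate numbers. The calls were lost without WT DMSO replicate 2 or WT Tg replicate 2 for ER chaperones (adjusted p up to 0.466), and without WT DMSO replicate 2 or WT Tg replicate 1 for the secretory list (up to 0.813) and ribosomal proteins (up to 0.931). They were lost without WT DMSO replicate 1 or either WT Tg library for mitochondrial mRNAs (up to 0.602). The ISR kinase call was lost without any 1 of WT DMSO replicate 2, both WT Tg and both DD DMSO libraries (up to 0.934). Without WT DMSO replicate 1 or WT Tg replicate 2 the ISR targets lay at −0.46 relative to all genes and passed (0.0201 and 0.0212), against −0.07 within each replicate number.

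**Figure D1:**
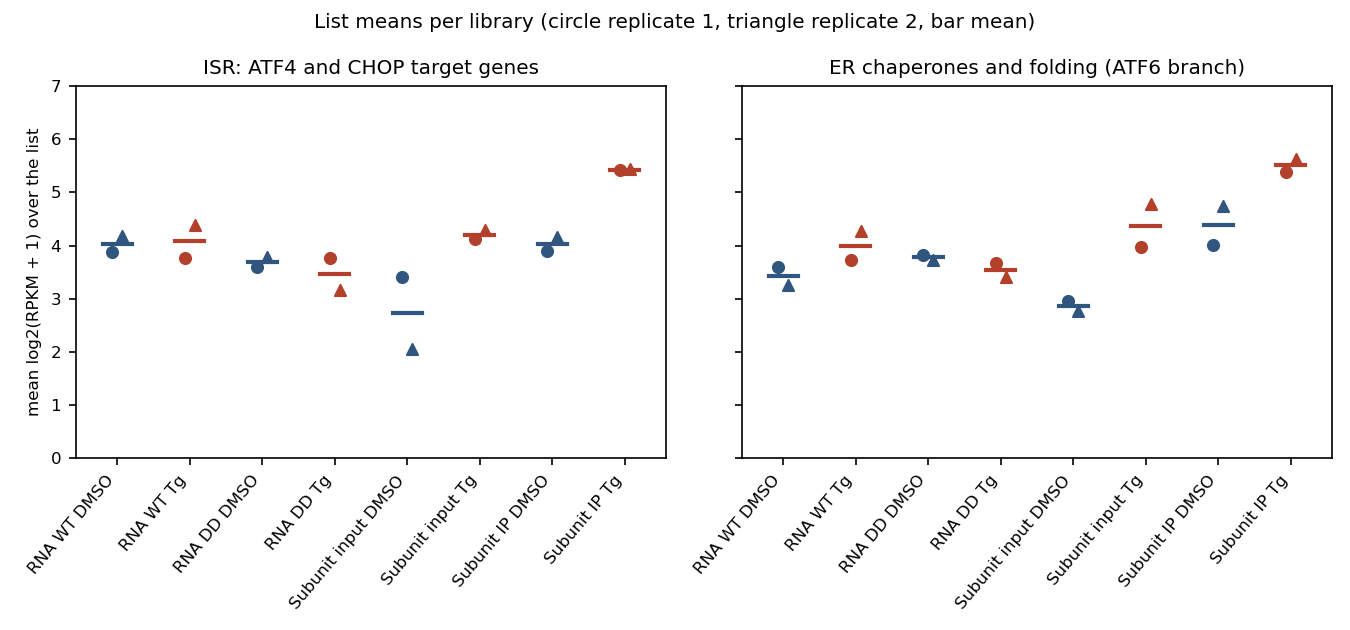
Mean log2(RPKM + 1) over the ATF4 and CHOP target genes (left) and over the ER chaperones and folding factors (right) in the 8 groups of libraries. Circles are replicate 1, triangles replicate 2 and bars their mean, with Tg in red and DMSO in blue; the ER chaperone mean was 2.96 and 2.77 in the Subunit-Seq inputs in DMSO and 3.97 and 4.78 in Tg, while the RNA-Seq libraries lay between 3.25 and 4.27.

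The same question was asked in DD cells. The 19 writers, erasers and readers of m6A rose by 0.30 relative to all genes (all-gene median 0.02), with 18 above the all-gene median. They include the RNA-binding proteins RBMX, at 25.1 ± 2.98 RPKM in DMSO and 36.6 ± 2.49 in Tg, and HNRNPC, at 40.4 ± 10.5 and 46.2 ± 0.789. Ribosomal protein mRNAs, which also passed in WT cells, changed by −0.71, with 7 of 75 above the all-gene median. RPS2 (ENSG00000140988.15), a small-subunit protein, averaged 5672 ± 4193 RPKM in DMSO and 2566 ± 1320 in Tg. DDIT3 averaged 37.6 ± 5.86 in DMSO and 17.8 ± 5.02 in Tg, a log2 difference of −1.05 ± 0.68 (SE), and EIF3D 57.1 ± 27.7 and 46.7 ± 24.9. ER chaperones lay 0.15 below all genes on the median (median −0.13, adjusted p = 0.129) and ISR targets 0.21 below (median −0.19, 0.0929), and neither passed.

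In DD cells limma called 0 genes, as did voom, with 25 at an unadjusted p under 0.05. The block left 0 (77 at an unadjusted p under 0.05), also without DD Tg replicate 2 (553). Camera gave adjusted p = 0.00355 for the m6A machinery and 2.06e-12 for ribosomal proteins, both with adjusted p = 0.749 with an estimated correlation. The other 19 lists had adjusted p from 0.058 to 0.955. Both calls differed between replicate numbers: relative medians were −0.10 in replicate 1 and 0.81 in replicate 2 for the m6A machinery, and 0.21 and −1.57 for ribosomal proteins. Without DD Tg replicate 2 both were lost (adjusted p of 0.953 for ribosomal proteins), and the m6A call was also lost without either DD DMSO library (up to 0.701). Without DD DMSO replicate 2 the secretory list passed at −0.50.

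Whether the response to Tg differed between DD and WT cells was tested as the interaction, where a negative value means a lower response in DD. ER chaperones fell by 0.69 relative to all genes on the log2 scale (median −0.78, all-gene median −0.10), with 0 of 23 members above the all-gene median, and the secretory list changed by −0.50. For HSPA5 the interaction was −0.78 ± 1.22 (SE), for DDIT3 −1.37 ± 0.96 and for EIF3D −0.19 ± 1.14. The 33 cell cycle genes of S, G2 and M phase rose by 0.41 and the 19 replication-dependent histone genes by 0.42. ISR targets had a median of −0.23 relative to all genes and did not pass (adjusted p = 0.474). The m6A machinery, which passed in DD cells and not in WT cells, did not pass here (adjusted p = 0.125), nor did ribosomal proteins (0.1005). The 17 lists that did not pass had adjusted p up to 0.839.

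Limma called 0 genes for the interaction, as did voom, with 21 at an unadjusted p under 0.05. The block left 0 (67 at an unadjusted p under 0.05), also without DD Tg replicate 2 (636). Camera gave adjusted p = 2.49e-05 for ER chaperones (adjusted p = 0.783 with an estimated correlation), 0.00433 for the secretory list, and 0.0181 for both cell cycle and histone genes (all 3 with adjusted p = 0.822 with an estimated correlation). Relative medians within replicates 1 and 2 were −0.32 and −1.59 for ER chaperones, −0.71 and −0.13 for the secretory list, 0.19 and 0.47 for cell cycle genes, and −0.64 and 1.57 for histones, which thus went opposite ways. The ER chaperone call was lost without WT DMSO replicate 2 (0.0759). The others were lost without WT DMSO replicate 2, WT Tg replicate 1, DD DMSO replicate 1 or DD Tg replicate 2 (adjusted p up to 0.958 for the secretory list, 0.552 for cell cycle genes and 0.966 for histones); the histone call was also lost without DD DMSO replicate 2, and the cell cycle call without WT DMSO replicate 1 or WT Tg replicate 2. Without DD Tg replicate 1 the m6A machinery passed at 0.73 and ribosomal proteins at −0.96 (2.13e-09), and without DD Tg replicate 2 ribosomal proteins passed at 0.33 (0.000369).

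The next question was whether DD cells differed from WT cells before stress. In DMSO the ISR targets fell by 0.33 relative to all genes on the log2 scale in DD cells (median −0.20, all-gene median 0.13), with 8 of 33 above the all-gene median. Mitochondrial mRNAs rose by 0.63 and the 20 cholesterol synthesis genes by 0.16. Histone genes changed by −0.33 and the 13 apoptosis regulators by −0.32. DDIT3 differed from the list it belongs to, with a log2 difference of 0.86 that did not pass. ATF4 averaged 263 ± 7.24 RPKM in WT and 291 ± 41.3 in DD. Camera's adjusted p was 4.21e-06 for ISR targets, 0.00202 for mitochondrial mRNAs and 0.0456 for apoptosis regulators, all with adjusted p = 0.551 with an estimated correlation. It was 0.00029 for histones (adjusted p = 0.668 with an estimated correlation) and 0.0456 for cholesterol synthesis (0.605 with an estimated correlation). The other 16 lists had adjusted p from 0.129 to 0.981.

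Limma called 0 genes between DD and WT cells in DMSO, with 68 at an unadjusted p under 0.05, and voom also called 0. The replicate block gave 0 with 227 at an unadjusted p under 0.05. With the block and without DD Tg replicate 2, a setting chosen after the data were seen, 974 genes had such a p and 3 passed as lower in DD cells: S100P, a calcium-binding protein, at −3.97 (adjusted p = 0.0246), SLC7A3, a cationic amino acid transporter, at −2.61 and RBP7, a retinol-binding protein, at −2.12 (0.041 for both). Relative medians within replicates 1 and 2 were −0.17 and −0.39 for ISR targets, 0.92 and 0.55 for mitochondrial mRNAs, 0.16 and 0.38 for cholesterol synthesis, −0.22 and −0.38 for apoptosis regulators, and 0.32 and −1.31 for histones, which went opposite ways. The ISR call was lost without DD DMSO replicate 1 or WT DMSO replicate 2 (adjusted p up to 0.289), the histone call without these or DD DMSO replicate 2 (up to 0.524), and the mitochondrial call without either DD DMSO library or WT DMSO replicate 1 (up to 0.518). The cholesterol call was lost without any 1 of the 8 libraries (up to 0.479) and the apoptosis call without any 1 of the WT and DD DMSO or WT Tg libraries (up to 0.29).

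Under Tg, ISR targets fell by 0.54 relative to all genes in DD compared with WT cells (median −0.49, all-gene median 0.05), with 5 of 33 above the all-gene median. ER chaperones fell by 0.34, with 3 of 23 above it, and the secretory list changed by −0.44. XBP1 (ENSG00000100219.16), a transcription factor of the unfolded protein response, averaged 115 ± 4.89 RPKM in WT and 59.9 ± 52.4 in DD. JUN (ENSG00000177606.6), a subunit of the AP-1 transcription factor, averaged 30.1 ± 14.1 and 18.8 ± 9.06. ALKBH5 (ENSG00000091542.8), an m6A demethylase, averaged 6.37 ± 0.822 and 5.20 ± 1.33. Camera's adjusted p was 1.67e-06, 0.00765 and 0.00838 for the ISR, ER chaperone and secretory lists, all with adjusted p = 0.765 with an estimated correlation, and 0.0877 to 0.954 for the other 18. Limma called 0 genes, with 82 at an unadjusted p under 0.05, and voom also called 0. The block left 0 (254 at an unadjusted p under 0.05), also without DD Tg replicate 2 (1052). Within replicates 1 and 2 the relative medians were −0.02 and −1.07 for ISR targets, −0.17 and −0.87 for ER chaperones and −0.43 and −0.54 for the secretory list. The ISR call was lost without WT Tg replicate 2 (adjusted p = 0.055), the ER chaperone call without that library or DD Tg replicate 1 (up to 0.453), and the secretory call without DD Tg replicate 2 or WT Tg replicate 1 (up to 0.741). Ribosomal proteins, which did not pass (0.107), turned from −0.92 (2.04e-08) without DD Tg replicate 1 to 0.44 (5.53e-05) without DD Tg replicate 2.

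The Subunit-Seq inputs gave a second look at the RNA response to Tg, in cells carrying the tagged eIF3d. All 31 tested ISR targets lay above the all-gene median (0.15), and the list rose by 1.33 relative to it. The 23 ER chaperones rose by 1.34, with all 23 above the all-gene median. The 20 cytosolic aminoacyl-tRNA synthetases, many of which are ATF4 targets, rose by 1.20, with 18 above it, and the 33 secretory genes by 0.81, with 31 above it. TRIB3 (ENSG00000101255.10), a pseudokinase induced by ATF4 and CHOP, rose from 11.3 ± 6.71 to 96.2 ± 43.7 RPKM (log2 3.02 ± 0.66 SE, adjusted p = 0.00985). HSPA5 averaged 11.4 ± 3.35 in DMSO and 82.5 ± 62.0 in Tg (adjusted p = 0.0909), DDIT3 6.52 ± 2.04 and 41.3 ± 12.4 (0.176) and ATF4 281 ± 210 and 506 ± 144, none of which passed. Histone genes also rose, by 0.84, while ribosomal proteins changed by −0.38 and mitochondrial mRNAs by −0.61.

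Limma called 5 of 9813 genes higher and 0 lower between the inputs, with 323 at an unadjusted p under 0.05 where chance gives 491. Without the replicate block 0 genes passed. The genes called besides TRIB3 were RN7SL2, RN7SL3, RN7SL4P and RN7SL5P, named after their values were seen. They belong to the 7SL family, the RNA of the signal recognition particle. The 7SL genes took 3.39% (95% Wilson interval 3.38 to 3.41) of reads in input Tg replicate 1 and at most 0.384% (0.379 to 0.388) in the other inputs. Voom called 0 genes, as did rescaled values, a fit on each gene's own spread, and fits without either input DMSO library, while fits without input Tg replicates 1 and 2 called 9 and 33. TRIB3 passed in 2 of the 8 fits that left out a library, those without an IP DMSO library (adjusted p up to 0.918 in the others). Adjusted over the list alone, 21 of 31 ISR targets, 14 of 23 ER chaperones, 4 of 20 synthetases, 1 of 33 secretory genes and 1 of 19 histone genes passed, against 1, 0, 0, 0 and 0 over all genes.

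For the inputs, camera's adjusted p was 1.74e-37 for ISR targets, 1.01e-31 for ER chaperones and 1.22e-17 for the secretory list (adjusted p = 0.34 with an estimated correlation for each), and 1.87e-14 for the synthetases (0.686 with an estimated correlation). These 4 calls held in all 8 fits that left out a library. Relative medians within replicates 1 and 2 were 1.03 and 1.70 for ISR targets, 1.37 and 1.35 for ER chaperones, 1.08 and 0.66 for the secretory list, and 0.55 and 1.70 for the synthetases. Adjusted p was 3.58e-09 for ribosomal proteins (0.784 with an estimated correlation), 7.43e-06 for mitochondrial mRNAs, a call lost after rescaling (0.0938), and 2.26e-07 for histones (both 0.694 with an estimated correlation). These 3 lists went opposite ways in replicates 1 and 2: 0.16 and −0.96, 0.04 and −1.20, and 2.15 and −0.56. Without input DMSO replicate 2 the ribosomal list turned to 0.20 (adjusted p = 0.0151) and the mitochondrial list to 0.33 (0.0401), while histones turned to −0.62 without input Tg replicate 1 (0.00324) and were lost without input DMSO replicate 1 (0.847). The other 13 lists had adjusted p from 0.0677 to 0.88.

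Which RNAs the cap-binding part of eIF3d recovered was asked by setting IP against input in DMSO. DBN1 (ENSG00000113758.13), which codes for the actin-binding protein drebrin, rose from 8.62 ± 7.88 RPKM in input to 527 ± 227 in IP, a log2 difference of 6.002 ± 0.638 (SE, adjusted p = 1.79e-17). SPTAN1 (ENSG00000197694.15), a spectrin, rose from 1.26 ± 1.31 to 90.7 ± 52.8 (5.35 ± 0.67, 1.97e-12), and DIAPH1, a formin, by 5.29 ± 0.67. EIF3A (ENSG00000107581.12), another eIF3 subunit, rose from 10.9 ± 13.8 to 278 ± 275 (4.88 ± 0.66, 1.47e-10), although the eIF3 list as a whole had a median of 0.05. JUN mRNA rose from 26.7 ± 32.3 to 138 ± 50.7 (3.10 ± 0.64, 0.00016), HSPA5 from 11.4 ± 3.35 to 110 ± 67.3 (3.04 ± 0.63, 0.000177) and ALKBH5 from 14.4 ± 17.8 to 62.8 ± 2.77 (2.84 ± 0.67, 0.00125). ATF4 rose from 281 ± 210 to 905 ± 445 (1.82 ± 0.46, 0.00285). EIF3D itself averaged 70.6 ± 46.8 in input and 156 ± 3.72 in IP (1.30 ± 0.59, 0.0848) and did not pass.

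Against the all-gene median of 0.96 in DMSO, the m6A machinery rose by 0.81 (11 of 19 members called higher, 13 adjusted over the list alone), the 16 cap-binding and 4E-BP genes by 0.85 (9 and 11), the apoptosis regulators by 0.83 (8 of 14 and 9) and the 13 cytosolic heat shock genes by 0.70 (8 and 8). ER chaperones rose by 0.62 (12 of 23 and 13), the 10 immediate early and AP-1 genes by 0.45 (4 and 5) and the 32 cell cycle genes by 0.38 (9 and 10). The 75 ribosomal protein mRNAs fell by 1.97 on the log2 scale relative to all genes, with 32 called lower and 38 adjusted over the list alone. The 19 histone mRNAs changed by −3.61 with 16 called lower on both counts, and the 13 mitochondrial mRNAs by −1.22 with 2 called higher and 3 lower (2 and 4 adjusted over the list alone). The 31 ISR targets lay 0.22 above all genes, with 8 called higher and 10 adjusted over the list alone, and the list did not pass (adjusted p = 0.0722), though it did without input DMSO replicate 1 (0.0131) or input Tg replicate 1 (0.0412).

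In DMSO limma called 2100 genes higher and 172 lower in IP of 9813, so 92.4% of calls were higher. Without the replicate block these counts were 21 and 3. After each library was rescaled to a common median, 12 were higher and 8 lower (60.0% higher), and among named genes DBN1, SPTAN1, DIAPH1 and EIF3A passed while HSPA5, JUN and ALKBH5 (adjusted p of 0.0949 to 0.097) and ATF4 (0.626) did not. Rescaling brought EIF3D to 0.00. Voom called 425 higher and 34 lower, and with median-ratio sizes 85 and 344, so the balance of higher and lower calls turned with the scaling. The prior on the spread had infinite degrees of freedom, so these adjusted p-values use the spread pooled over genes and are too small for genes with a large spread of their own. On each gene's own spread 0 genes passed, with 1746 at an unadjusted p under 0.05 against 4042. Leaving out a library moved the count of genes called higher by more than 1.5 times in all 8 fits. The count rose without input DMSO replicate 1 and fell in the other 7 fits, furthest without input DMSO replicate 2. Without input DMSO replicate 2 the adjusted p was 0.0737 for DBN1, 0.074 for SPTAN1, 0.101 for DIAPH1, 0.107 for EIF3A and 0.494 for ATF4. JUN, HSPA5 and ALKBH5 were lost without that library or IP DMSO replicate 2 (up to 0.345, 0.306 and 0.364), and ATF4 also without IP DMSO replicate 1 (0.065).

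Camera's adjusted p in DMSO was 1.65e-49 for ribosomal proteins and 2.64e-37 for histones (both with adjusted p = 0.464 with an estimated correlation), and these held in all 8 fits that left out a library and after rescaling. IP over input increased with transcript length in each pair of libraries, and the list tests, here and in Tg, did not account for this. For the other lists called, adjusted p with an estimated correlation was 0.879. They had 0.00665 (m6A machinery, lost without IP DMSO replicate 2 at 0.0873), 0.0187 (ER chaperones, lost without IP or input DMSO replicate 1, up to 0.173) and 0.0269 (cap-binding genes, lost without IP or input DMSO replicate 2, up to 0.289). Cell cycle genes had 0.0318, lost without the same pair of libraries (up to 0.513). Apoptosis regulators (0.0289), mitochondrial mRNAs (0.000991), immediate early genes (0.0269) and heat shock genes (0.0269) were lost without IP DMSO replicate 1 or input DMSO replicate 2 (up to 0.0791, 0.508, 0.0791 and 0.115). After rescaling the m6A machinery (0.00658) and immediate early genes (0.042) still passed and the other 6 lists of this kind did not (0.0701 to 0.296). Relative medians within replicates 1 and 2 were −1.0001 and −2.88 for ribosomal proteins, −3.65 and −3.25 for histones, 0.40 and 1.19 for the m6A machinery, 0.55 and 0.51 for ER chaperones, 0.16 and 1.26 for cap-binding genes, 0.69 and 0.76 for apoptosis regulators, 0.50 and 0.77 for immediate early genes, 0.51 and 1.17 for heat shock genes, −0.54 and −2.10 for mitochondrial mRNAs, and −0.08 and 0.89 for cell cycle genes, which went opposite ways. The other 10 lists had adjusted p from 0.0722 to 0.906. For the eIF3 subunits (adjusted p = 0.658) the median of 0.05 and the mean of 0.73 were positive, both below the all-gene median, while the test against other genes was negative.

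In Tg the recovered RNAs were asked for in the same way. DBN1 rose from 6.83 ± 1.21 RPKM in input to 618 ± 88.3 in IP (6.31 ± 0.64, adjusted p = 1.04e-19), SPTAN1 from 1.02 ± 0.101 to 145 ± 60.2 (6.11 ± 0.67, 5.34e-17) and EIF3A from 7.59 ± 4.92 to 280 ± 175 (5.01 ± 0.66, 1.90e-11). These 3 passed in all 8 fits that left out a library and after rescaling. JUN rose from 27.9 ± 17.6 to 344 ± 42.5 (3.72 ± 0.64, 9.23e-07) and JUND, a related AP-1 subunit, from 21.6 ± 4.75 to 245 ± 111 (3.38 ± 0.64, 1.68e-05). HSPA5 rose from 82.5 ± 62.0 to 388 ± 90.0 (2.43 ± 0.63, 0.00305), ALKBH5 from 15.3 ± 6.83 to 95.5 ± 10.8 (2.63 ± 0.67, 0.00239) and ATF4 from 506 ± 144 to 1320.3 ± 40.7 (1.41 ± 0.46, 0.0249). EIF3D averaged 169 ± 125 in input and 218 ± 53.1 in IP (0.58 ± 0.59, 0.471). RN7SL2 (ENSG00000274012.1) averaged 56828 ± 70917 in input and 472 ± 80.5 in IP, a log2 change of −5.83 ± 0.37. That SE comes from the spread pooled over genes. The 7SL genes took 3.39% of reads in input Tg replicate 1 and 0.209% in input Tg replicate 2.

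Relative to the all-gene median of 0.87 in Tg, the m6A machinery rose by 0.63 (8 of 19 called higher, 11 adjusted over the list alone), apoptosis regulators by 0.83 (7 and 10) and immediate early genes by 0.37 (3 and 5). Ribosomal protein mRNAs changed by −1.94 (32 called lower and 44 adjusted over the list alone), histones by −4.34 (18 and 18) and mitochondrial mRNAs by −1.22 (2 and 2). ISR targets lay 0.44 above all genes, with 7 called higher and 9 adjusted over the list alone (adjusted p = 0.195), and ER chaperones, with 6 and 10, did not pass either (0.325). Camera's adjusted p was 2.48e-54 for ribosomal proteins (adjusted p = 0.416 with an estimated correlation) and 2.9e-68 for histones (0.259 with an estimated correlation), kept in all 8 fits that left out a library. It was 0.0182 for the m6A machinery and for apoptosis regulators, 0.047 for immediate early genes and 1.72e-05 for mitochondrial mRNAs, each with adjusted p = 0.978 with an estimated correlation. The first was lost without IP or input Tg replicate 2 (up to 0.141), the apoptosis and mitochondrial calls without IP Tg replicate 2 (0.141 and 0.295), and the immediate early call without any library other than input Tg replicate 2 (up to 0.141) and after rescaling (0.0588). Relative medians within replicates 1 and 2 were −2.18 and −1.76 for ribosomal proteins, −6.04 and −2.82 for histones, 0.20 and 0.91 for the m6A machinery, 0.58 and 0.81 for apoptosis regulators, 0.49 and 0.69 for immediate early genes, and −0.23 and −2.19 for mitochondrial mRNAs. The other 14 lists had adjusted p from 0.123 to 0.932; for the eIF3 subunits (0.261) the median of −0.42 and the mean of 0.36 differed in sign, and the list passed after rescaling (0.0225).

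In Tg limma called 1432 genes higher and 159 lower (90.0% higher), with 3423 at an unadjusted p under 0.05 and 1724 on each gene's own spread, of which 0 passed. Without the replicate block 24 were higher and 12 lower. After rescaling 28 were higher and 36 lower (43.8% higher). Voom called 109 higher and 51 lower, and with median-ratio sizes 49 and 161 (23.3% higher), so the balance turned here too. After rescaling JUN, JUND, HSPA5, ALKBH5 and ATF4 did not pass (adjusted p of 0.0806, 0.0607, 0.209, 0.166 and 0.824). JUN was lost without IP Tg replicate 2 (0.147), HSPA5 without either IP Tg library or input Tg replicate 1 (up to 0.263), ALKBH5 without IP Tg replicate 2 or either input Tg library (up to 0.478), and ATF4 without IP Tg replicate 2, input Tg replicate 1 or either input DMSO library (up to 0.646). Without a library the count of changed genes was 114 (input Tg replicate 1), 135 with 36 of them higher (IP Tg replicate 2), 279 (IP Tg replicate 1), 300 (input Tg replicate 2), 2897 (input DMSO replicate 2) and 2905 (input DMSO replicate 1). Of the genes called higher, 1133 were called in both treatments, where independent lists share 306, and of those called lower 109 were, against 2.79. Both contrasts came from 1 fit with 1 pooled spread, so a large overlap carries no separate weight.

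**Figure D2:**
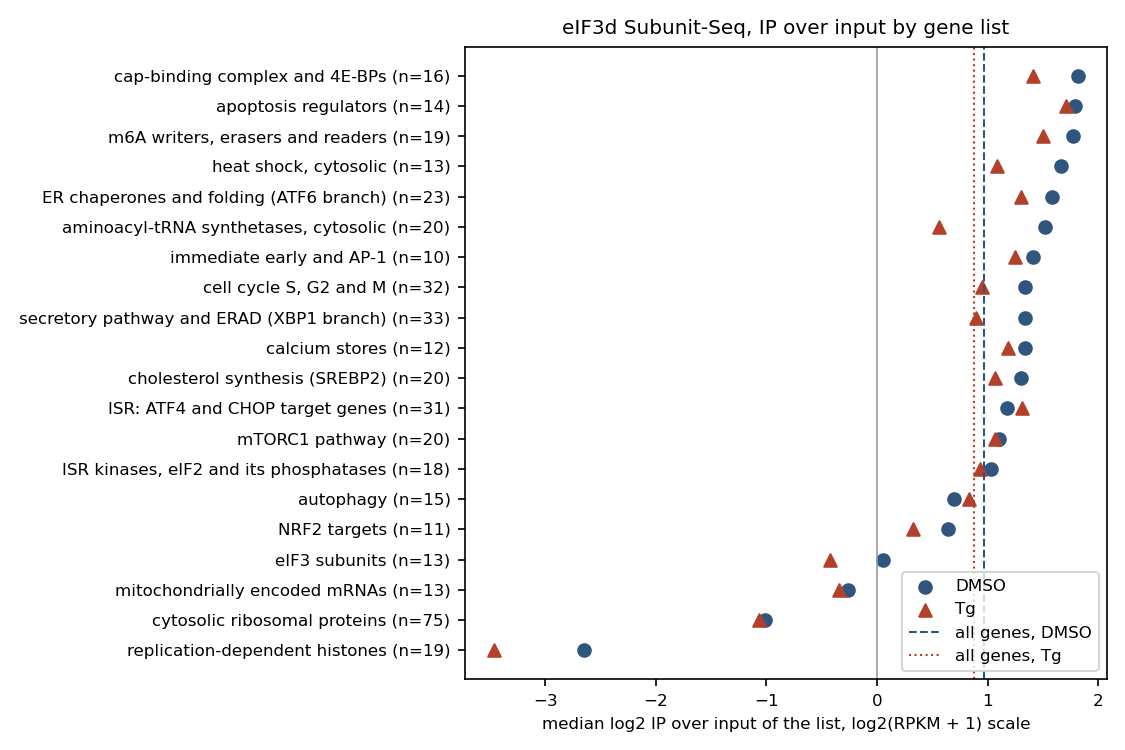
Median log2 difference of IP over input, on the log2(RPKM + 1) scale, of the 20 gene lists with their number of tested members; blue circles are DMSO, red triangles Tg, and the dashed and dotted lines the all-gene medians of 0.96 and 0.87. Histone and ribosomal protein mRNAs lie farthest below the lines, a direction that rescaling kept, whereas the all-gene medians themselves go to 0.01 in both treatments. The lists were not matched on transcript length.

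Whether Tg changed the recovery of RNAs was tested as IP over input in Tg against DMSO. The aminoacyl-tRNA synthetases changed by −0.65 relative to all genes (all-gene median −0.07), with 0 of 20 above the all-gene median. ER chaperones changed by −0.45 (4 of 23 above), cell cycle genes by −0.39 (5 of 32) and histones by −1.13 (1 of 19). SARS1, the seryl-tRNA synthetase, had a difference of −0.60 ± 0.90 (SE), HSPA5 of −0.61 ± 0.89, JUN of 0.62 ± 0.90, ATF4 of −0.41 ± 0.66, ALKBH5 of −0.21 ± 0.94 and EIF3D of −0.72 ± 0.84, and none passed. ISR targets lay 0.11 below all genes (median −0.17, adjusted p = 0.669), with relative medians of 0.30 and −0.37 within replicates 1 and 2; they passed at −0.59 without input DMSO replicate 1 (0.0442) and at 0.16 without input DMSO replicate 2 (0.0294). So ER chaperone mRNAs were called in the DMSO but not the Tg recovery, and the difference itself passed with the preset correlation.

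Camera's adjusted p for that difference was 8.52e-06 for the synthetases, 0.0132 for ER chaperones, 0.00111 for cell cycle genes and 2.21e-18 for histones, all with adjusted p = 0.982 with an estimated correlation. Within replicates 1 and 2 the relative medians were −0.03 and −1.30, −0.08 and −0.54, −0.05 and −0.75, and −2.60 and 0.43. The synthetase call was lost without input DMSO or input Tg replicate 2 (up to 0.301), the cell cycle call without input DMSO replicate 2, IP DMSO replicate 2 or IP Tg replicate 1 (up to 0.991), and the histone call without input DMSO or input Tg replicate 1 (up to 0.764). The ER chaperone call was lost without IP DMSO replicate 1, IP Tg replicate 2, input DMSO replicate 1 or input Tg replicate 2 (up to 0.834). Adjusted over the list alone, 2 histone genes and 0 members of the other 3 lists passed. The other 16 lists had adjusted p from 0.0566 to 0.948. Limma called 0 genes higher and 6 lower, with 86 at an unadjusted p under 0.05; voom, rescaled values and each gene's own spread called 0, and fits without 1 library called 0 (either input DMSO library or input Tg replicate 1), 1 (IP DMSO replicate 2), 3 (IP Tg replicate 1), 13 (IP DMSO replicate 1) and 19 (input Tg replicate 2). The lower genes, named after their values were seen, were RN7SL2, RN7SL3, RN7SL4P, RN7SL5P, MIR3929 and MT-RNR1. Without the replicate block 0 genes passed.

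The IP libraries were also compared directly between Tg and DMSO, a contrast chosen after the data were seen. ISR target mRNAs rose by 1.29 relative to all genes (all-gene median 0.07), with all 31 above the all-gene median, ER chaperones by 0.97 with all 23 above it, the secretory list by 0.65 with 32 of 33, and the synthetases by 0.56 with 16 of 20. NUPR1, a stress-induced ATF4 target, rose from 2.89 ± 1.36 to 28.7 ± 25.0 RPKM (log2 2.66 ± 0.63, adjusted p = 0.0401). LBH, a transcription cofactor, rose by 3.11 ± 0.61 and OSTN, which codes for the secreted peptide musclin, by 2.98 ± 0.60 (0.00379 for both). NUPR1 was lost without any 1 of the 8 libraries, and LBH and OSTN without either input DMSO library, IP DMSO replicate 1 or either IP Tg library (adjusted p up to 1.00 for each), LBH also without IP DMSO replicate 2. DDIT3 averaged 14.96 ± 2.63 in IP DMSO and 129 ± 109 in IP Tg (0.0555). Camera's adjusted p was 2.36e-47 for ISR targets, 1.29e-24 for ER chaperones (both with adjusted p = 0.341 with an estimated correlation) and 1.04e-14 for the secretory list (0.404 with an estimated correlation), kept in all 8 fits that left out a library. It was 0.0014 for the synthetases (0.99 with an estimated correlation), lost without IP DMSO or IP Tg replicate 1 (up to 0.715). Relative medians within replicates 1 and 2 were 1.39 and 1.19 for ISR targets, 1.26 and 0.84 for ER chaperones, 0.77 and 0.61 for the secretory list and 0.66 and 0.36 for the synthetases.

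Lower in the IP of Tg were ribosomal proteins at −0.42 relative to all genes (adjusted p = 1.23e-17, 0.608 with an estimated correlation), with −0.88 and 0.06 in replicates 1 and 2, and mitochondrial mRNAs at −0.57 (9.74e-14, 0.404 with an estimated correlation), with 0.30 and −1.54. The ribosomal call was lost without IP DMSO replicate 1 (0.765), and mitochondrial mRNAs turned to 0.46 without IP Tg replicate 2. Histones (−0.41, adjusted p = 8.21e-05), cholesterol synthesis (−0.31, 0.0163) and cell cycle genes (−0.21, 0.0218) passed but were lost without IP DMSO replicate 2 or IP Tg replicate 1 (up to 0.765, 0.671 and 0.671), the cholesterol call also without IP Tg replicate 2. The other 11 lists had adjusted p from 0.0632 to 0.962. Limma called 5 genes higher and 2 lower, with 165 at an unadjusted p under 0.05; voom, rescaled values and each gene's own spread called 0, and fits without 1 library called 0 (either input DMSO library), 2 (IP DMSO replicate 2), 3 (IP Tg replicate 2 or input Tg replicate 1), 12 (IP Tg replicate 1) and 24 (IP DMSO replicate 1). Adjusted over the list alone 13 of 31 ISR targets and 4 of 23 ER chaperones passed, against 1 and 0 over all genes. Without the replicate block 0 genes passed over all genes.

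The m6A-eCLIP lists asked where methylated adenosines were called with and without stress in each genotype. They held 3000 sites in WT DMSO, 1572 in WT Tg, 1796 in DD DMSO and 5050 in DD Tg, so the list under Tg was shorter in WT and longer in DD. Sites on the mitochondrial genome numbered 599, 490, 513 and 694, most of them on the ribosomal RNAs, and the remaining 2401, 1082, 1283 and 4356 were nuclear, in 1287, 664, 724 and 2177 genes. In genes at 1 RPKM or more, 1452, 611, 741 and 2761 nuclear sites kept that order. Among nuclear genes, RPL36, a large-subunit ribosomal protein, had 19, 7, 14 and 27 sites, RACK1, a ribosome-bound scaffold, 14, 2, 8 and 26, and EEF2, the translation elongation factor, 9, 7, 7 and 25. Of 77 ribosomal protein genes, 54, 30, 33 and 58 had a site. Of the 1495, 626, 765 and 2956 sites placed within the span of a nuclear protein-coding gene, 24.1%, 23.6%, 25.6% and 28.2% lay in the last 10% of that span. The end of the span was set by the strand of the site, not of the gene.

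ISR targets with a site numbered 11 of 35 in WT DMSO, 6 in WT Tg, 5 in DD DMSO and 16 in DD Tg, and ER chaperones 4, 1, 0 and 11 of 24. The synthetases numbered 8, 5, 4 and 10 of 20 and the ISR kinases, eIF2 subunits and phosphatases 3, 2, 1 and 4 of 19. As the lists differ in length, shares say more than counts: the ISR targets held 0.708%, 0.647%, 0.390% and 0.597% of nuclear sites, the synthetases 0.541%, 0.555%, 0.312% and 0.505%, and the ISR kinase list 0.167%, 0.277%, 0.156% and 0.161%. The ER chaperones held 0.167%, 0.0924%, 0% and 0.390%. Genes of the m6A machinery with a site numbered 0, 1, 0 and 6 of 22: RBM15, YTHDF1, YTHDF2, IGF2BP1, HNRNPA2B1 and HNRNPC in DD Tg and HNRNPA2B1 in WT Tg. EIF3D had 4 sites in WT DMSO, on the minus strand of chromosome 22 (GRCh38) at 36510932, 36511575, 36511649 and 36519539, the last of which was its single site in WT Tg, and none in either DD list. ATF4, on chromosome 22, had 1 site in WT DMSO, 2 in WT Tg, 0 in DD DMSO and 2 in DD Tg, and the site at 39522136 was in both Tg lists. EIF2B1, a subunit of the exchange factor that recycles eIF2, had sites at 123621362 and 123621379 of chromosome 12 in every list, and GDF15, a stress-induced secreted factor, had a site at 18388973 of chromosome 19 in all 4. IRE1-dependent decay substrates had 0 sites.

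**Figure D3:**
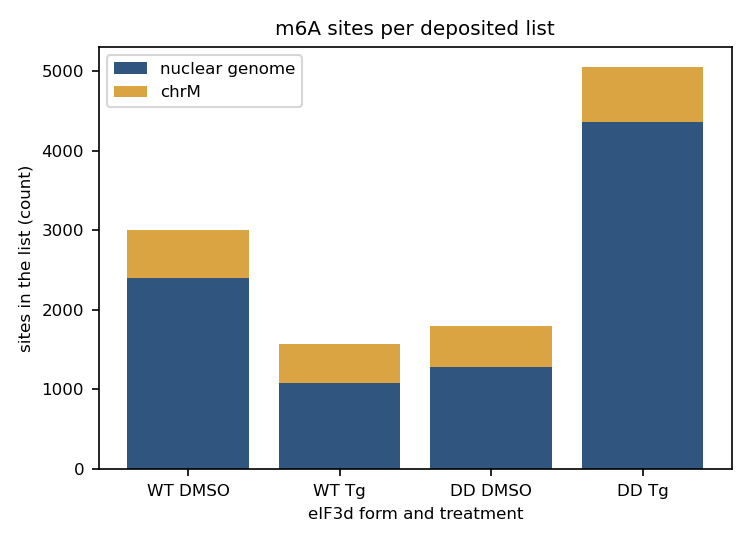
Number of called m6A sites in each of the 4 deposited lists, as stacked bars of sites on nuclear genes or regions and on the mitochondrial genome. Nuclear sites range from 1082 in WT Tg to 4356 in DD Tg, while mitochondrial sites stay between 490 and 694; each list is a single pooled call with no replicates, and no scaling was applied.

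The lists shared 757 sites by position and strand across all 4, of which 384 were nuclear. Nuclear genes with a site in all 4 lists, whether or not the same site, numbered 319. WT DMSO and WT Tg shared 595 nuclear sites, DD DMSO and DD Tg 808, WT DMSO and DD DMSO 687, and WT Tg and DD Tg 709. By genes at 1 RPKM or more, WT DMSO and WT Tg shared 323 against 42.0 for independent lists, and DD DMSO and DD Tg 390 against 78.4, of 9156 genes. The overlaps of independent lists were not matched on expression. Nuclear sites found in 1 list alone numbered 1076 in WT DMSO, 289 in WT Tg, 387 in DD DMSO and 2831 in DD Tg. Of the 3000 WT DMSO sites, mitochondrial ones included, 1652 lay in a gene with a site in WT Tg. In a gene with a site in DD DMSO lay 1709 of them.

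Whether genes with gained or lost sites also differed in RNA or in eIF3d recovery was asked against 10000 random gene lists matched on expression. The 1125 genes with a site in DD Tg and none in DD DMSO had a median RNA difference (DD Tg minus DD DMSO) of 0.00, above all matched lists (median −0.09), but at percentile 8.93 of lists without matching, so the direction turned with the background. The 84 genes with a site in DD DMSO and none in DD Tg had a median of 0.12, at percentile 99.8 of matched lists but 95.2 without matching, within the middle 95%. For the 555 genes with a site in WT DMSO and none in WT Tg the median RNA difference in WT cells was 0.08. It lay at percentile 4.17, within the middle 95% of matched lists, but at 0.07 without matching. The 469 genes with a site in DD DMSO had a median IP over input in DMSO of 0.45 against 0.71 for matched lists, at percentile 0.01, whereas the 847 genes with a site in WT DMSO were at percentile 51.3. Without matching both sets were at percentile 0, so the contrast between them depended on the matching. The 117 genes with a site in WT Tg and none in WT DMSO had a change of IP over input with Tg of −0.16, at percentile 1.57. These are 20 comparisons across genes, which are not independent replicates, and the IP was made from 1 cell line only. Neither kind of random list was matched on transcript length, with which IP over input increased in each pair of libraries. The percentiles of IP over input therefore cannot be told apart from an effect of length.

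Markers of other cell types were low or few. In RNA-Seq the highest blood marker was HBA2 at a mean of 0.990 RPKM, the highest liver marker APOA1 at 0.626, the highest epithelial marker KRT10 at 23.6 and the highest fibroblast marker COL1A1 at 8.06. In Subunit-Seq the highest were HBA2 at 4.44, APOA1 at 0.701 and KRT10 at 34.2, and the fibroblast markers reached 7.20. None of these lists had 5 tested members, so none was tested.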

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

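The tests of the spread between replicates, of swapped labels and of mitochondrial site calls were chosen after the results they bear on had been seen, as were the robust prior, voom and the length trend after rescaling. The bounds for the first of these tests and for swapped labels were widened by the gap between replicate numbers in WT cells (0.97) after their values were seen.

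In the difference of IP over input between Tg and DMSO, 6 genes passed on their own: RN7SL2 at −4.32, RN7SL4P at −4.22, RN7SL3 at −4.12, MIR3929 at −3.81, RN7SL5P at −3.65 and MT-RNR1 at −1.56 (log2, adjusted p from 1.05e-12 to 0.015). All 6 calls were lost with a robust prior, with rescaling and with voom, and without input Tg replicate 1 or either input DMSO library (RN7SL2 ranged from −6.72 to −1.92 among these). Lists whose IP over input differed between treatments had medians of −0.72 (aminoacyl-tRNA synthetases), −0.51 (ER chaperones), −0.46 (cell cycle) and −1.20 (histones). Lists whose response to Tg differed between DD and WT in RNA-Seq had medians of −0.78 (ER chaperones), −0.59 (secretory pathway), 0.32 (cell cycle) and 0.33 (histones). None of these 8 list differences passed with an estimated correlation, a test that also missed the changed list in the simulation.

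No single gene of the ER chaperone list passed in RNA-Seq after Tg, and in WT cells the list rose by less than in the Subunit-Seq inputs at the same dose and time. The list was already higher in RNA-Seq without Tg. Its mean log2(RPKM + 1) was at least 3.25 in every RNA-Seq DMSO library, against 2.96 and 2.77 in the DMSO inputs. Whether a raised level in the controls made the rise smaller stays open. The assays used different library kits, so their levels cannot settle it. A response in WT cells hidden by the spread between replicates stays open, because the list median was 1.03 in replicate 2 and 0.07 in replicate 1. In DD cells the list medians were −0.10 and −0.50 in replicates 1 and 2, with 10 of 23 members higher in each. A hidden response stays open there only because −0.10 lies below the bound of 0.5 by less than the WT gap of 0.97. Exchanged labels stay open too, since the best exchange of 2 of the 8 labels gave at least 0.31 in both replicate numbers, short of 1 by less than that gap. A difference between the lines that carry WT, DD and tagged eIF3d is a biological explanation that was not tested.

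IP over input increased with effective transcript length across genes in each of the 4 pairs of libraries. Low depth of the inputs was argued against, since the lowest correlation was 0.25 over the 7619 genes with at least 20 reads in every input. Reads taken by mitochondrial and structural RNA, which would lower all other genes by a single factor per library, were argued against, since the longest 25% of genes exceeded the shortest by at least 0.36 (log2), and by 0.355 to 2.70 after that factor was removed by rescaling. A length bias of the protocol stays open: Spearman's rho across genes, which are not independent replicates, was 0.19, 0.54, 0.29 and 0.36, and 0.19 lies between the bounds set for and against it. A preference of eIF3d for some transcripts over others is a biological explanation that was not tested apart from length.

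The DD Tg site list was longer and the WT Tg list shorter than their DMSO lists. Mitochondrial calls were argued against as the source, since the DD Tg list held 4.03 times the nuclear sites of the WT Tg list. The 1157 genes with a site in DD Tg and none in WT Tg had a median RNA difference of 0.014 (log2, DD minus WT). This argued against a rise in RNA shared by these genes. The median lay at percentile 95.3 of matched random lists and at 2 without matching, and changes in single genes stay open. Deeper or more sensitive calling in the longer list stays open, because 65.5% of nuclear WT Tg sites were also in the DD Tg list and neither depth nor replicates are known. A response of methylation to Tg that depends on the eIF3d form stays open as well, untested.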

How the results depend on the processing

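The settings voom, voom with median-ratio sizes, robust prior, own spread, and block without DD Tg replicate 2 were chosen after the data were seen, as were the contrast of IP Tg with IP DMSO and the definition of a list's value as its distance from the all-gene median. With 2 libraries per group, and a lone library in a group assumed to vary like the other groups when 1 is left out, no call rests on its own group's spread. Of 2314 list values under other settings, 2117 counted as the same, 148 fell below the threshold, 45 passed it and 4 turned. Of 5457 values of named genes, 4502, 951, 4 and 0 did. Without 1 library the list values numbered 1640, of which 1466 counted as the same, 98 fell below, 49 passed and 27 turned. A change of direction counted as a turn only if the value passed in the main or the other setting. Values counted as the same can thus have changed direction without passing in either. The stricter site score could not be run. Depth limits the genes near 1 RPKM, and the simulation at a dispersion of 0.3 recovered 10.4% of genes changed 4-fold. The cause of the changes below was not tested, except that fewer samples or genes enter where a library or a filter is named.

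An estimated correlation and fry called 0 lists in every contrast. The estimated correlation also missed the changed list in the simulation, and fry was not run there. In RNA-Seq (5, 2, 5, 3 and 4 lists called for WT Tg, DD Tg, DD against WT in DMSO and in Tg, and the interaction), a filter at 5 RPKM gave 6 lists for DD Tg, 3 for DD against WT in DMSO and 1 in Tg. No filter gave 1 list for DD Tg, 3 and 5 for DD against WT in DMSO and in Tg, and 2 for the interaction. Fitting only the groups compared gave 3 lists for DD against WT in DMSO. The block without DD Tg replicate 2 gave 1 list for DD Tg and 3 changed genes for DD against WT in DMSO; it turned ribosomal proteins to 0.26 (DD Tg), 0.68 (DD against WT in Tg) and 0.64 (interaction) and the m6A machinery to −0.29 (DD Tg).

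In Subunit-Seq, genes higher and lower in IP against input in DMSO were 12 and 8 with rescaling, 0 and 0 with no filter, 21 and 3 with no block, 1227 and 105 with a pseudocount of 0.1, 0 and 0 with own spread, 425 and 34 with voom, 85 and 344 with voom and median-ratio sizes, and 562 higher with a filter at 5 RPKM. In Tg they were 28 and 36, 0 and 0, 24 and 12, 355 and 92, 0 and 0, 109 and 51, 49 and 161, and 289 higher. For the difference between treatments, 0 genes were lower with rescaling, no filter, no block, the other pseudocount, robust prior, own spread and both kinds of voom. For the inputs, 0 were higher with these except robust prior (1). For IP Tg against IP DMSO, 0 were higher or lower with rescaling, no filter, no block, own spread and both kinds of voom; a filter at 5 RPKM gave 2 higher and 0 lower, the other pseudocount 0 and 1, and robust prior 8 higher. Rescaling left 4 and voom with median-ratio sizes 5 of the 10 lists in DMSO, and no block gave 7 lists for the difference between treatments. Without matching, percentiles turned to 0 for genes with a site in DD Tg (IP against input in Tg) and in WT DMSO (IP against input in DMSO), to 8.93 (DD Tg and not DD DMSO) and to 2 (DD Tg and not WT Tg, RNA DD against WT), and others moved to 0.02 (WT Tg), 95.2 (DD DMSO and not DD Tg) and 0.07 (WT DMSO and not WT Tg). The other pseudocount moved the percentile of the change in IP over input to 0.785 (DD Tg and not DD DMSO), 1.57 (WT DMSO and not DD DMSO) and 0.62 (WT Tg and not DD Tg). By gene, 1709 WT DMSO sites, mitochondrial ones included, lay in a gene with a site in DD DMSO and 1652 in one with a site in WT Tg.

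Without 1 library at a time, RNA-Seq called 0 to 0 genes in each contrast. Lists called ranged from 1 to 6 for WT Tg, where list values ranged from −0.46 to 0.26 (ISR targets), −0.73 to 0.10 (ribosomal), −0.95 to 0.69 (histones) and −0.0047 to 0.54 (secretory). They ranged from 0 to 4 for DD Tg (m6A machinery −0.078 to 0.75), 0 to 4 for DD against WT in DMSO (histones −1.32 to 0.27), 1 to 5 in Tg (ribosomal −0.92 to 0.44, histones −0.50 to 0.34) and 1 to 7 for the interaction (ribosomal −0.96 to 0.33, histones −0.34 to 1.27). In Subunit-Seq IP against input in DMSO, 0 to 4937 genes were higher, 0 to 150 lower and 5 to 11 lists called, and in Tg 36 to 2745, 38 to 163 and 2 to 6. For the difference between treatments these were 0 to 2, 0 to 17 and 2 to 8 (ISR targets −0.59 to 0.17, ribosomal −0.67 to 0.60, mitochondrial mRNAs −1.18 to 1.04, histones −2.59 to 0.28). For the inputs they were 0 to 30, 0 to 3 and 7 to 9 (cell cycle −0.18 to 0.45, ribosomal −1.05 to 0.20, mitochondrial −1.47 to 0.33, histones −0.62 to 2.35). For IP Tg against IP DMSO they were 0 to 9, 0 to 15 and 5 to 10 (cell cycle −0.50 to 0.022, ribosomal −0.98 to 0.13, mitochondrial −1.71 to 0.46, histones −1.03 to 0.046).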

Other observations

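The site counts in this part were not tested, and no test was chosen after its result was seen. Mitochondrially encoded mRNAs held 127 of 599 mitochondrial sites in WT DMSO, 44 of 490 in WT Tg, 60 of 513 in DD DMSO and 220 of 694 in DD Tg. Replication-dependent histone mRNAs held 27, 5, 13 and 49 sites (1.12%, 0.462%, 1.01% and 1.12% of nuclear sites). Genes of the cap-binding complex and the 4E-BPs, which control cap-dependent initiation, held 10, 2, 3 and 27 (0.416%, 0.185%, 0.234% and 0.620%). KHDC1 held 6, 6, 8 and 12 sites, counted on either strand, at a mean of only 0.585 RPKM in RNA-Seq.

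The writers METTL3 (ENSG00000165819.11) and METTL14 (ENSG00000145388.14), which form the core m6A methyltransferase, and EIF2AK4 (ENSG00000128829.11), which codes for the ISR kinase GCN2, did not pass in any RNA-Seq contrast. METTL3 averaged 1.99 RPKM in WT DMSO, 2.45 in WT Tg, 3.16 in DD DMSO and 2.98 in DD Tg. METTL14 averaged 1.02, 1.18, 1.15 and 1.74, and EIF2AK4 0.976, 1.16, 1.21 and 1.98. In Subunit-Seq EIF2AK4 rose from 1.91 ± 2.42 RPKM in input to 6.93 ± 0.946 in IP in DMSO (log2 1.75 ± 0.61 SE, n = 2, limma adjusted p = 0.0275), a call lost after rescaling (0.151) and in 6 fits without 1 library (up to 0.582, without IP DMSO replicate 2; kept without IP DMSO or input DMSO replicate 1), while METTL3, at 0.49, did not pass (adjusted p = 0.554).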
